A study of Arabidopsis thaliana with 4 samples.

How the data were processed

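Transcript levels were measured in roots of wild-type Col-0 (2 samples) and of the nlp7-1 mutant (2 samples). Per the labels, plants grew at 22 °C with 16 h days on agar with 1x MS salts, and biotin-labelled cRNA was made from 1 µg of total RNA by a single amplification cycle. The series design text calls the samples biological replicates. The deposited values are intensities per probe set on a linear scale, made with MAS5 per the submitters' processing notes, and the version is not given in the sources used here. In all 4 arrays the mean signal after trimming 2% at each end was 250.0, so the arrays had been scaled to a common level. Signals ran from 0.03 to 18276. No detection calls were used, and scanner images were not analysed here.

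The table holds 22810 probe sets, of which 64 are controls and were left out of the tests. GEO's platform annotation names 1 gene for 13513 of the other 22746 probe sets, several genes for 503 and none for 8730, which are unnamed here. Symbols were updated through gene identifiers in the RefSeq gene table of assembly TAIR10.1, which placed 13436 probe sets. Because the files name no genome build, this table was used only for names and gene order, and no coordinates are given. Of the 52 genes with several kept probe sets, 1 had a call and probe sets of opposite sign.

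Values were taken to log2 with no pseudocount and no further normalization. Probe sets were kept when their mean log2 over the 4 samples was at or above the 40th percentile, a signal of 59.4, which left 13648. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment. Standard errors of log2 changes are those of the moderated fit, and folds are 2 to the power of the log2 change. The fit was tested on simulated data with the levels of the 13648 probe sets, in 20 simulations with 200 changed probe sets each. Variances were drawn from the prior of the fit itself, with independent normal noise. It called 94.4% of 4-fold, 49.0% of 2-fold and 5.60% of 1.5-fold changes with the right sign. Of all simulated calls, 4.17% were unchanged probe sets. This rate holds under the assumptions of the fit and is not a measure of the error rate in the 4 arrays.

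The design, the test, the named-gene rule, 26 gene lists by locus and 6 family rules were fixed before the data were examined. Lists were tested with camera in limma (preset correlation 0.01) using the brightest probe set per gene, when 5 or more members were measured, which held for 5 of the 32 lists. Only 73 of the 509 entries of the locus lists had a named probe set. The rule named 14 genes of the root cap and of nitrate signalling whatever their values, of which 1 had a named probe set. It then took the 12 largest increases and 12 largest decreases among named probe sets past the test without overlap, and up to 4 members with the smallest p of each tested list. Family rules that need gene descriptions were applied to the symbols and synonyms of the gene table.

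After the calls were seen, the log2 changes of 7267 genes (1 probe set each, limited to 1.5 in size) were scanned in gene order for runs of 10 to 400 neighbours whose mean departs from that of all genes. The strongest run was compared with 1000 shuffled orders (Python 3.11.15, numpy 2.4.6). A run with a permutation p of at most 0.01 was then taken out and the scan repeated on the remaining genes with 1000 new shuffles, until a run did not pass, which was the third. In 5 simulated data sets on the same 7267 genes, with 100 neighbours shifted by 0.5, at least 99 of the 100 were recovered.

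Alternatives were other filters on low signals, pseudocounts of 32 and 100, quantile normalization, median centring, other variance priors, an unmoderated test, the replicate number as a block, and each sample left out. For lists they were an estimated correlation, fry and the mean of all probe sets of a gene. Fits without the genes of the chromosome 1 run were added after the data had been seen.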

Results

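The series measured steady-state transcript levels in whole Arabidopsis roots, cut off where root meets hypocotyl at an age given as 5 dai. The 2 genotypes were the Col-0 accession and the nlp7-1 mutant, which carries a lesion in NLP7. NLP7 (NIN-LIKE PROTEIN 7) encodes a transcription factor of nitrate signalling. Each genotype had 2 biological replicates of about 60 roots, hybridised to 4 Affymetrix ATH1 arrays. The comparison asks which root transcripts differ in level between mutant and wild type under standard growth, with no treatment. The median MAS5 signal was 100.8 and 97.5 in the wild-type samples and 99.5 and 99.3 in the mutant samples. No probe set was named for NLP7 in the annotation used here, so the mutated gene could not serve as a check of the genotype labels. With 2 samples per genotype, the number of arrays limits the precision of every value below.

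Among the 13648 probe sets kept, the 2 mutant samples correlated with each other at r = 0.986 across probe sets, and the 2 wild-type samples at r = 0.978. Pairs of different genotype correlated at 0.961 to 0.977. The highest of these, wild type replicate 1 with nlp7-1 replicate 1, was nearly as high as the wild-type pair, so the arrays did not group clearly by genotype. Probe sets are not independent replicates, and these values describe the arrays only. The SD of the log2 difference between replicates was 0.314 in wild type and 0.247 in nlp7-1, and 0.317 to 0.420 between samples of different genotype. The 3' to 5' signal ratio of control probe sets is a sign of RNA integrity. For 1 pair of actin probe sets it was 9.88 and 15 in wild type and 12.3 and 12.6 in nlp7-1. Another actin pair had lower ratios, 1.97 and 2.75 in wild type and 2.23 and 2.49 in nlp7-1. GAPDH had 1.37 and 1.28 in wild type and 1.28 and 1.57 in nlp7-1, and ubiquitin 2.72 and 2.68, and 2.64 and 2.89. The signal of the 25S rRNA control probe set did separate the genotypes, at 5005 and 5318 in wild type and 6180 and 6248 in nlp7-1.

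Among named genes, a pair of lipid-transfer-protein-like genes and an osmotin gene were among those that fell most in nlp7-1 roots, and most of the genes that rose lay close together on chromosome 1. AT4G12490, of the lipid-transfer-protein-like family, fell by 2.71 ± 0.21 on the log2 scale (SE). Its signal was 657 ± 103 in wild type and 102 ± 28 in nlp7-1 (SD, n = 2; limma adjusted p = 0.0150). Its relative AT4G12500, at a neighbouring locus, fell by 2.16 ± 0.24 (adjusted p = 0.0186). OSM34, an osmotin of the thaumatin-like family, fell by 2.11 ± 0.34, from a signal of 2310 ± 773 to 548 ± 240 (SD, n = 2; limma adjusted p = 0.0371). AT1G73120 rose the most among named genes, 4.16-fold, from 382 ± 116 to 1553 ± 123 (SD, n = 2; limma adjusted p = 0.0186).

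In all, 310 probe sets differed between the genotypes at a Benjamini-Hochberg adjusted p under 0.05 in limma. Of these, 224 were higher and 86 were lower in nlp7-1, and 305 also differed by at least 1.5-fold. At an unadjusted p under 0.05, 1802 probe sets passed where chance gives 682, and at 0.01 the numbers were 763 and 136. In 44.1% of kept probe sets the genotypes did not overlap, where chance gives 33.3% for 2 against 2. Only 128 of the higher and 42 of the lower probe sets name a single gene here. With 1 sample left out, the spread comes only from the genotype that keeps 2 samples, and it was wider in wild type than in nlp7-1. Counts of calls from such fits therefore also reflect which pair set the spread, and are not compared here. In all 310 calls the genotypes did not overlap, so leaving out a sample could not change a sign. The count was 116 when the variance prior had no trend, and 0 with an unmoderated two-sample test. The unmoderated test gave 1371 at an unadjusted p under 0.05.

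Further genes with the largest decreases were AT1G70880 (3.46-fold lower) and AT5G38900 (2.74-fold). AT2G29340, a short-chain dehydrogenase gene, was 2.58-fold lower, from 412 ± 81 to 159 ± 16 (SD, n = 2). AT4G33960 was 2.38-fold lower. In 5 genes that fell, the mutant signal lay below the filter level of 59.4, so signals are given in place of folds. AT4G37290, AT2G23270 and AT3G09405 went from 151 ± 38, 146 ± 45 and 153 ± 31 to 33.9 ± 7.7, 39.7 ± 1.5 and 48.8 ± 3.0 (SD, n = 2). AT4G01390 went from 118 ± 34 to 45.4 ± 2.5, and PIFI, whose product acts in chloroplast electron flow, from 117 ± 6 to 46.6 ± 9.8. By the rule that picked them, all 12 passed with both mutant samples below both wild-type samples. The adjusted p of these 12 genes in limma ran from 0.0150 for AT4G12490 to 0.0493 for AT4G01390. OSM34, AT4G01390 and PIFI no longer passed when the chromosome 1 genes described below were left out of the fit, with adjusted p of 0.0581, 0.0764 and 0.0556.

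Besides AT1G73120, the named genes with the largest increases outside that chromosome 1 group were AT4G32950 and AT3G61930. AT4G32950, of the protein phosphatase 2C family, rose from 50.2 ± 4.1, below the filter level, to 154 ± 13 (SD, n = 2). AT3G61930 rose by 1.43 ± 0.15 on the log2 scale, from 151 ± 12 to 411 ± 66. The other 9 of the 12 genes with the largest increases all lay in the chromosome 1 group. AT1G27200 rose 3.43-fold, and AT1G23030, a U-box ubiquitin ligase gene, 2.66-fold. AT1G22160 and AT1G27120 rose from wild-type signals below the filter level, 51.5 ± 5.5 and 44.2 ± 2.1, to 177 ± 23 and 117 ± 9. LPR1, a multicopper oxidase gene of the root response to low phosphate, rose 2.52-fold, from 69.2 ± 13.0 to 174 ± 23 (SD, n = 2; limma adjusted p = 0.0284). AT1G24560 and AT1G22170 both rose 2.39-fold, AT1G23410 rose 2.38-fold and AT1G26460 rose 2.34-fold. Of these 24 genes, 6 no longer passed in limma without a trend in the variance prior and 3 without a filter on low signals. With a sample left out, no sign could change, since the 24 were picked for no overlap between genotypes. Log2 changes then ran from -2.99 to -2.42 for AT4G12490, -2.57 to -1.64 for OSM34 and 1.74 to 2.37 for AT1G73120. With a pseudocount of 100, the log2 change of 13 of the 24 was over 1.5 times smaller. It was -0.90 and not -2.15 for AT4G37290, -0.80 and not -1.84 for AT2G23270, and 0.76 and not 1.62 for AT4G32950. AT4G01390 no longer passed in limma with pseudocounts of 32 and 100 (adjusted p = 0.0570 and 0.0672). AT1G22170 no longer passed with the filter at the median (limma adjusted p = 0.0529).

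**Figure D1:**
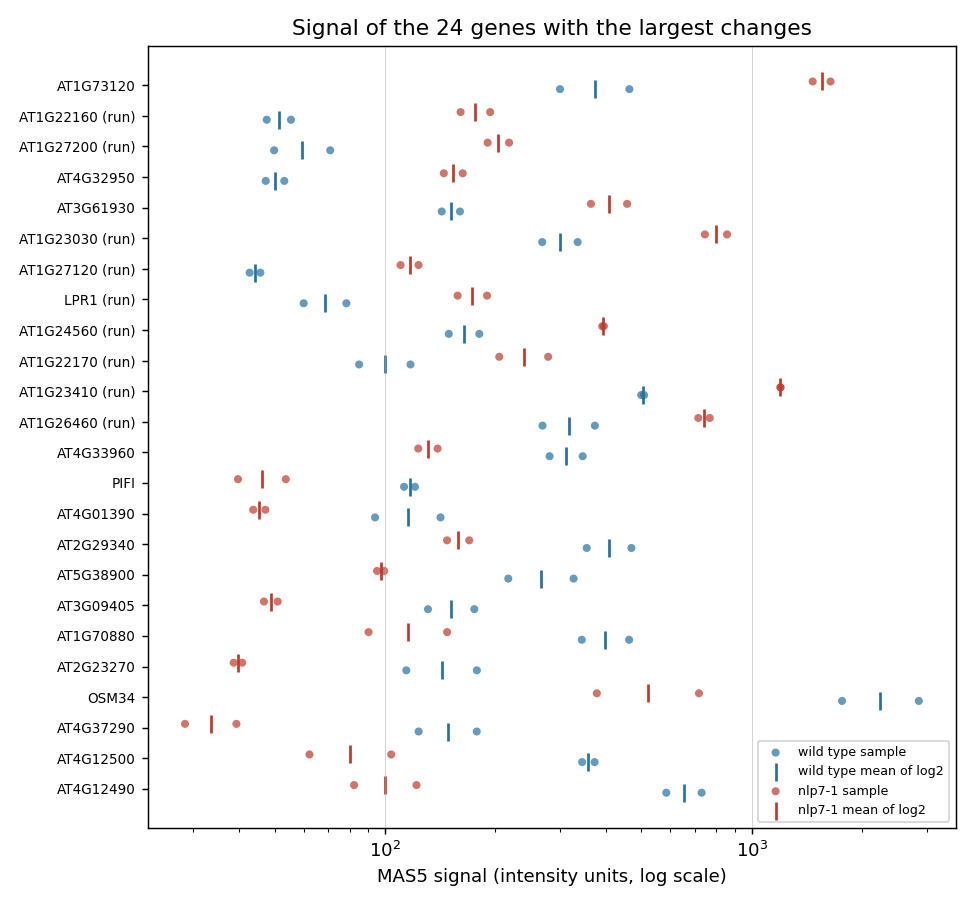
MAS5 signal (horizontal, log scale, intensity units) of the 12 genes with the largest decreases and the 12 with the largest increases in nlp7-1. Points are samples (2 per genotype), ticks are means of log2 signal, and genes marked "run" belong to the chromosome 1 group. By the rule that picked them, the genotypes do not overlap in any of the 24 genes.

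Probe sets without a gene name included some larger changes. Probe set 253502_at was 8.53-fold higher in nlp7-1, from 71.9 ± 11.2 to 614 ± 104 (SD, n = 2; limma adjusted p = 0.00963). Probe sets 245038_at and 267565_at fell from 474 ± 347 and 324 ± 202 to 30 ± 14 and 24 ± 17 (SD, n = 2; limma adjusted p = 0.0284 and 0.0359), mutant signals below the filter level.

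The higher transcripts were not spread evenly over the genome. The distribution along the chromosomes was examined after the calls had been seen, using only the order of genes. A run of 193 neighbouring measured genes on chromosome 1, from AT1G20910 to AT1G27530, had a median log2 change of 0.84, or 1.79-fold. The gene annotation holds 621 protein-coding genes in this stretch, so most of them were not measured under a gene name. Outside the run, the median over 7074 genes was -0.001. Of the run genes, 190 were above 0, and in 184 both mutant samples exceeded both wild-type samples. That is 95.3% of the run, against 21.8% of the genes outside. Chance gives 16.7% for genes not picked by their change. Because the run was picked for its shift, its share only describes it. No shuffled gene order among 1000 gave a run as strong (permutation p = 0.001, the smallest that number allows, two-sided over runs of either direction). The run holds 2.66% of the genes placed on the 5 chromosomes. It holds 111 of the 128 named probe sets that rose, and 0 of those that fell.

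The genes of the run have varied roles. CYTC-1, which encodes cytochrome c, rose 1.60-fold from a signal of 5284 ± 246 to 8470 ± 207 (SD, n = 2). UGT85A2, a glycosyltransferase gene, rose 1.94-fold, LSM3A, of the RNA-binding LSM complex, 1.85-fold, and LCR, an F-box gene, 1.77-fold. These 4 were picked as named examples after their values were seen. The median log2 change was 0.08 over the 10 measured genes before the run and 0.86 over the first 10 within it. At the far end the medians were 0.79 within and 0.06 after it. Because the scan set both ends from these same values, part of the contrast there is built in. The shift of run genes relative to other genes was between 0.81 and 0.87 in each of the 4 pairings of a mutant with a wild-type sample. It was -0.004 between the 2 wild-type samples and -0.06 between the 2 mutant samples. When the named run genes were left out before the fit, 105 probe sets differed, 63 higher and 42 lower. Probe sets not naming 1 gene, which include 96 of the 224 higher calls, were not placed and stayed in that fit. All 105 had also passed in the fit as designed, where only 17 named probe sets outside the run were higher. At most 17 of the 63 are therefore known to lie outside the run. The others have no known place and may lie in it.

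**Figure D2:**
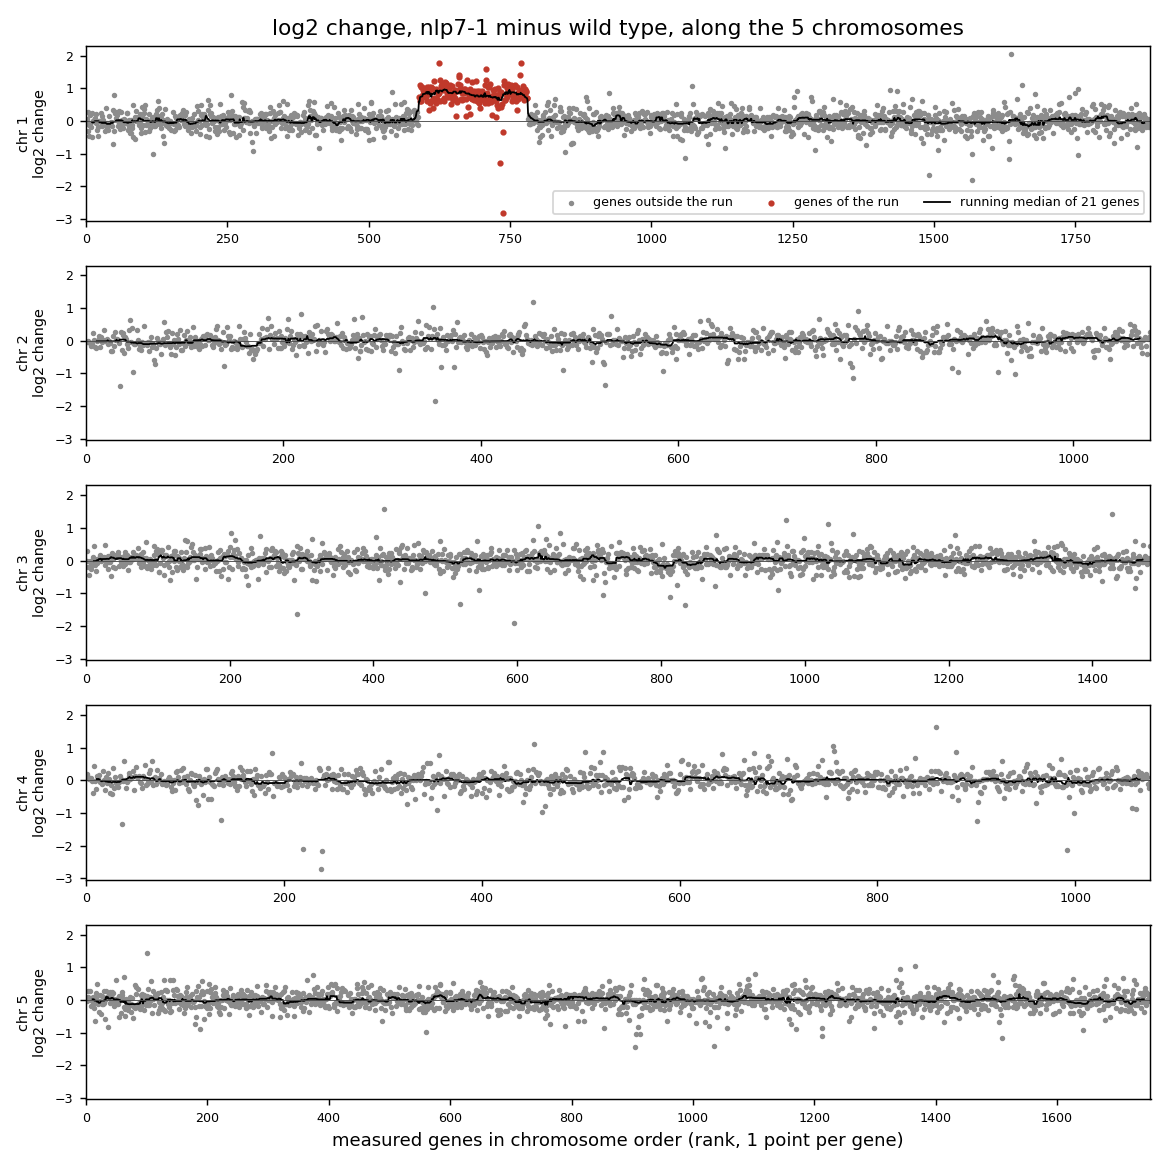
Log2 change (nlp7-1 minus wild type, vertical) of each measured gene in its order along each of the 5 chromosomes (rank, horizontal), 1 point per gene, with the running median of 21 genes. The 193 genes of the run on chromosome 1 are in red and have a median of 0.84, and the running median elsewhere stays near 0.

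**Figure D3:**
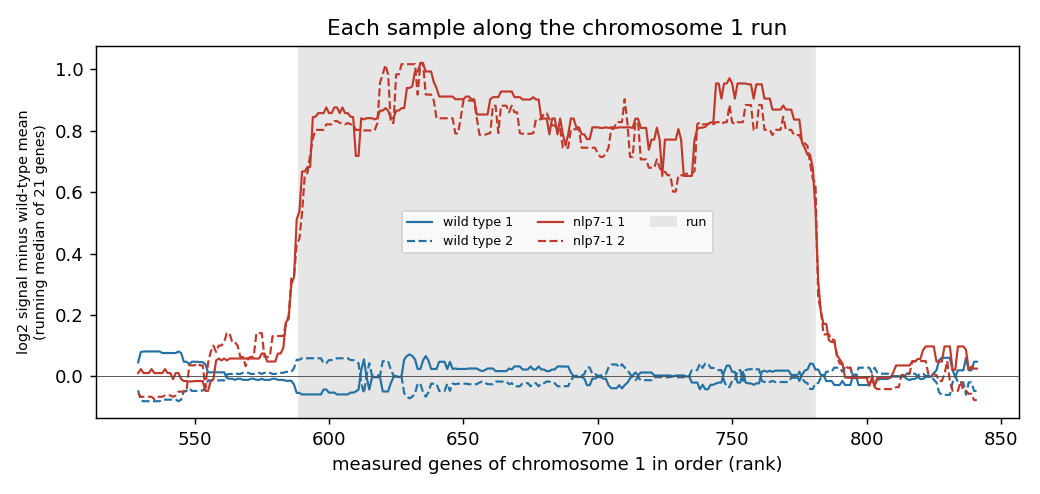
Log2 signal of each of the 4 samples minus the wild-type mean, as a running median of 21 genes, for the run on chromosome 1 (grey) and 60 genes on each side. Both mutant samples rise at the start of the run and return at its end.

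For nitrate, the question was whether genes of the primary nitrate response differed in the mutant. Of the 31 list members, 5 were measured under a gene name, and 0 passed the limma test, also adjusted over the list alone, with 1 at an unadjusted p under 0.05. AT1G68670 (HHO2), a repressor of nitrate responses, had a log2 change of -0.28 ± 0.11 (SE). PGD1 (AT1G64190) and PGD3 (AT5G41670), of the pentose phosphate pathway, had -0.16 ± 0.09 and 0.12 ± 0.13. AT1G25550 (HHO3) lies in the chromosome 1 run and had 0.12 ± 0.11. With a sample left out, PGD3 ran from 0.015 to 0.23 and HHO3 from 0.063 to 0.18. The list as a whole did not pass (camera adjusted p = 0.577), with only 5 of 31 members measured. Its mean log2 change was -0.03 and its median 0.05, of opposite sign. The mean turned to 0.05 without nlp7-1 replicate 2 and to 0.03 without wild type replicate 1. With all samples but without HHO3, the mean of the other 4 members was -0.07 (camera unadjusted p = 0.338). In the nitrate transport list, 2 members were measured: AT2G26690 (NRT1.4) had a log2 change of 0.51 ± 0.12, which passed only when adjusted over the list alone. NIA1, NIA2, NIR1, NRT1.1, NRT2.1 and NRT3.1 had no named probe set and are not analysed here.

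For the root cap, whose outer layers are shed as border-like cells, 5 of the 24 list members were measured. Of these, 0 passed the limma test either over all probe sets or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The list as a whole did not pass (camera adjusted p = 0.416). Its mean log2 change was 0.26, and it was 0.54 without wild type replicate 1 and -0.02 without wild type replicate 2. RCPG (AT1G65570), a root cap polygalacturonase gene, had the largest difference, 0.94 ± 0.32 on the log2 scale (SE), with signals of 57.0 ± 24.6 in wild type and 105 ± 20 in nlp7-1 (SD, n = 2). Its limma adjusted p was 0.280, and its log2 change was 1.4 without wild type replicate 1 and 0.49 without wild type replicate 2. PASPA3 (AT4G04460), SCPL48 (AT3G45010) and EXI1 (AT2G14095), markers of root cap cell death, had log2 changes of 0.16 ± 0.26, 0.08 ± 0.16 and 0.13 ± 0.25, which turned to -0.09, -0.10 and -0.21 without wild type replicate 2. PASPA3 also turned negative without nlp7-1 replicate 2 (-0.12), and SCPL48 without nlp7-1 replicate 1 (-0.04). SMB, BRN1, BRN2, FEZ, CEL5 and CEL3 had no named probe set and are not analysed here.

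Among cell wall families, the list of cellulose synthase family and cellulase genes was higher in nlp7-1 (mean log2 change 0.27 over 10 measured members, camera adjusted p = 0.0194 with a preset correlation). With an estimated correlation the list had an adjusted p = 0.760, so the call was lost. The measured members were 5 cellulose synthase-like (CSL) genes, some of which make other wall polysaccharides, and 5 cellulase genes, and 0 were CESA genes, which encode the synthases of cellulose itself. The mean log2 change of the list fell to 0.04 without wild type replicate 2 and to 0.12 without nlp7-1 replicate 1. The mean was 0.50 without wild type replicate 1 and 0.42 without nlp7-1 replicate 2. In limma 0 members passed over all probe sets, 3 had an unadjusted p under 0.05, and 1 passed when adjusted over the list alone: CSLA03, a mannan synthase gene within the chromosome 1 run, at 0.81 ± 0.16. GH9B13, GH9B7 and CSLC04 had log2 changes of 0.58 ± 0.17, 0.29 ± 0.11 and 0.35 ± 0.16. With a sample left out, log2 changes ran from 0.62 to 1.00 for CSLA03, 0.34 to 0.81 for GH9B13 and 0.15 to 0.56 for CSLC04.

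Xyloglucan endotransglucosylases had 7 measured members. In limma 0 passed over all probe sets, 4 had an unadjusted p under 0.05, and 4 passed when adjusted over the list alone, 3 of them higher. XTH18, XTH19 and XTH16 had log2 changes of 1.05 ± 0.20, 0.91 ± 0.28 and 0.57 ± 0.18, and XTH20 had -0.57 ± 0.18. With a sample left out, log2 changes ran from 0.75 to 1.36 for XTH18, 0.45 to 1.37 for XTH19 and 0.32 to 0.82 for XTH16. The list as a whole did not pass (camera adjusted p = 0.401). Its mean log2 change ran from 0.03 to 0.59 with a sample left out. Expansins, which loosen walls, had 10 measured members, of which 0 passed in limma over all probe sets or adjusted over the list alone, and 1 had an unadjusted p under 0.05. EXPB1 had 0.74 ± 0.22, EXPA4 -0.55 ± 0.23, EXPA18 0.36 ± 0.22 and EXPA15 0.32 ± 0.22 (list camera adjusted p = 0.538). EXPB1 and EXPA15 had 1.07 and 0.64 without wild type replicate 1. Leaving out a sample gave ranges of 0.41 to 1.07 for EXPB1, -0.83 to -0.26 for EXPA4, 0.11 to 0.61 for EXPA18 and -0.0088 to 0.64 for EXPA15. Without wild type replicate 2, EXPA15 had the lowest of these and the mean of the expansin list turned from 0.10 to -0.03.

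In the lists with fewer than 5 measured members, only single genes can be given. SWEET11, a sucrose transporter gene of the phloem, rose 2.18-fold (limma adjusted p = 0.0430). GH3.3, which encodes an auxin-conjugating enzyme, rose 2.06-fold (limma adjusted p = 0.0350), while the other 2 measured auxin response genes did not pass. With a sample left out, log2 changes ran from 0.93 to 1.32 for SWEET11 and from 0.85 to 1.23 for GH3.3. Of 4 iron deficiency genes, AT3G12900 (S8H) had a log2 change of 1.58 ± 0.29 and AT3G13610 (F6H1) -0.65 ± 0.18. Both act in coumarin synthesis and passed only when adjusted over the list alone. The same held for 4 further genes of these small lists. LTI30, a dehydrin gene, had -0.36 ± 0.08, and PDC2, a pyruvate decarboxylase gene of the hypoxia list, -0.39 ± 0.11. UGT74B1, of glucosinolate synthesis, and GI, a clock gene, had 0.55 ± 0.11 and 0.51 ± 0.18 and lie in the chromosome 1 run. PDC2 and GI were the only measured members of their lists, where this adjustment changes nothing. Of 3 touch and wounding genes, which can respond to handling, CML38 had 0.98 ± 0.32 with no overlap between genotypes and did not pass (limma adjusted p = 0.244, and 0.0570 adjusted over the list alone). WRKY53 and STZ had 0.23 ± 0.46 and 0.05 ± 0.18. In all, 9 small lists, those of handling, root hair, heat shock, sulfur deficiency, mitotic, flavonoid, sugar starvation, pectin and peroxidase genes, had 19 measured members. In limma 0 of them passed over all probe sets or adjusted over the list alone, with 3 at an unadjusted p under 0.05. The shoot markers LHCB4.1, LHCB4.2 and RCA had -0.64 ± 0.21, -0.39 ± 0.25 and -0.02 ± 0.11, and 0 of them passed in limma, with 1 at an unadjusted p under 0.05.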

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

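All alternatives were planned except leaving out the run and the settings for its shift, chosen after the data were seen. No call in the fit as designed changed sign with quantile normalization or median centring. The other alternatives could not change a sign. They keep the log2 change as it is, or drop a sample or add a pseudocount where no call overlapped between genotypes. Filters, pseudocounts, quantile normalization, centring and a robust prior gave 238 to 326 differing probe sets. Without a trend there were 116 (85 higher, 31 lower, all 116 past 1.5-fold), of which all had passed before. The unmoderated test gave 0 in either direction, and 1371 at an unadjusted p under 0.05. With each sample left out, where the lone sample is assumed to vary like the other genotype, totals ran from 14 to 770 (higher 6 to 502, lower 8 to 268, past 1.5-fold 14 to 728, unadjusted 1093 to 2748). Without the named run genes there were 105 (63 higher, 42 lower, 105 past 1.5-fold), and 94 of the 199 calls left in were lost. In that fit fewer small p-values enter the adjustment, which tightens it, and the variance prior is refitted. Probe sets not naming 1 gene stayed in, so these calls are not all known to lie outside the run. The replicate block gave 1290 (701 higher, 589 lower, 717 past 1.5-fold, 3055 unadjusted); no label ties same-numbered samples, whose replicate differences correlated at 0.436 between genotypes. Under the block, 9 more of the named genes passed: RCPG, EXPB1, EXPA4, XTH16, XTH18, XTH19, XTH20, CSLA03 and GH9B13.

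The run's shift over other genes was 0.84, and 0.73 and 0.62 with pseudocounts of 32 and 100, which shrink low signals, and 0.80 to 0.86 with a sample left out. Of 5 lists, 1 passed as designed, 0 with an estimated correlation, 0 with fry, 0 without the run genes when adjusted over the same 5 lists, and 0 to 3 with a sample left out. With a sample left out, mean changes ran from -0.034 to 0.242 for expansins, -0.024 to 0.544 for root cap genes and -0.113 to 0.052 for nitrate genes, and log2 changes from -0.12 to 0.43 for PASPA3 (AT4G04460), -0.10 to 0.26 for SCPL48, -0.21 to 0.46 for EXI1 (AT2G14095) and -0.0088 to 0.642 for EXPA15. Other causes were not tested. The NLP7 level had no value under any setting. Signals near the filter limit detection of low transcripts.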

Other observations

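The tests of the chromosome 1 run, of the plastid and nuclear photosynthesis sets and of the control ratios, and the list test without the run, were chosen after the data were seen. Several loci fixed in advance lie within the run by gene order but have no named probe set: the root cap genes CEL5, FEZ, RNS3 and PIN7, the phloem genes SUC2 and SULTR1;3, and FRO3. The measured neighbours of CEL5, a cellulase gene of the root cap, were AT1G22870 and AT1G22885, with log2 changes of 0.95 and 0.71 (limma adjusted p = 0.0281 and 0.0356). Those of FEZ were AT1G26850 and AT1G26880, with 0.96 and 0.81. A few run genes departed from the common shift: AT1G26380 had -2.80, AT1G26250 -1.28 and AT1G26420 -0.33, and AT1G25550 (HHO3) had 0.12, the 4th lowest of 193. The 20 measured genes nearest NLP7 on chromosome 4 had a median of -0.04, a range of -0.25 to 0.24, with 0 calls in limma and 0 at an unadjusted p under 0.05.

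Other genes that fell, chosen after their values were seen, were CHI (AT2G43570), a chitinase gene, at 2.02-fold, ARPN, which encodes plantacyanin, at 1.96-fold, and DLAH, a lipase gene, at 1.91-fold. A second run, of 13 genes on chromosome 5 from AT5G38900 to AT5G39840, had a median log2 change of -0.26 (permutation p = 0.005). Its standardized mean departure was 6.21, below the highest of 7.41 in 1000 shuffled orders. It begins with AT5G38900, at -1.45, which is among the 12 genes with the largest decreases. The next strongest run, of 11 genes on chromosome 1 from AT1G70500 to AT1G70880, had a median of -0.28 and did not pass (permutation p = 0.214).

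The chromosome 1 run of higher transcripts was set against 2 explanations. Regulation of single genes downstream of NLP7, placed without regard to gene order, was argued against as the whole account by the scan statistic (the run's standardized mean departure), which was 37.4 against at most 6.48 in 1000 shuffled orders. A candidate explanation is an extra copy of this segment in the nlp7-1 line: the median of 0.84 lies between log2 of 3 over 2 copies (0.58) and of 4 over 2 (1.00), and run genes of low, middle and high signal had medians of 0.73, 0.86 and 0.83. A regional change of transcription, or fewer copies in the wild-type stock, stays open without DNA measurements.

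Plastid-encoded transcripts were lower in nlp7-1 (median log2 change -0.22 over 53 genes, 46 below 0), and psaB and rbcL passed the limma test. The camera p of this set was 3.45e-09 with the preset correlation and 0.0835 with an estimated one, both unadjusted. Less shoot tissue in the mutant samples stays open: 9 nuclear photosynthesis genes had a median of -0.45 (camera unadjusted p = 0.00319 preset, 0.387 estimated), but against each gene's mean the set's medians were -0.0074 and 0.362 in wild type and -0.425 and 0.032 in nlp7-1, which overlap, and RCA went only from 375 to 371. RNA degradation or labelling stays open too, since 0 of 3 control ratios of 3' to 5' signal separated the genotypes while the 25S rRNA signal did. A genotype effect on plastids cannot be told apart from these with 2 samples each.

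The higher list of cellulose synthase-like and cellulase genes could reflect its member in the run, CSLA03. Without the run genes its mean log2 change was 0.21 against 0.27, a fall of 21.9%, and its camera adjusted p was 0.0590 over the same 5 lists, against 0.0194 with them. It was 0.0472 over the 4 lists that keep 5 measured members, so whether the run accounts for the list stays open. Over its alternatives the adjusted p ran up to 0.760, so whether the list differs at all stays open.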
